A study of Mus musculus with 24 samples.

How the data were processed

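Liver RNA of 24 mice, 1 library per mouse, was sequenced in 5 groups: LF_C (n = 4), HF_C, HF_KO, HF_TZD_C and HF_TZD_KO (n = 5 each). Per the labels, RNA was extracted from whole liver with Trizol and the libraries were not strand specific. The names LFCF and HFCF of the diets are used as given. According to the submitters' notes, the authors aligned reads with STAR 2.6.1 to GRCm38/mm10, counted them per gene with HTSeq 0.6.1 and tested with DESeq2. The annotation release is not stated, and gene positions, lengths and biotypes are those the tables give.

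The authors deposited 5 tables, each comparing a pair of groups. The deposited read counts are whole numbers per gene and sample without normalization, and all results here start from them. The authors' normalized signal is the counts divided by 1 size factor per sample and table. The authors' FPKM values are counts per kilobase of gene length, scaled by the reads of the sample in the table, and the deposited gene length (a unit of its own kind) is in bases. The authors' log2 fold changes are shrunken towards 0, and their p-values are given with adjusted ones (unit p-value). The tables were joined by gene identifier into 24137 genes, 17879 of them protein-coding, with 0 counts that differed between tables. A gene that a table left out had a count of 0 in its samples wherever another table gave it. Of the identifiers, 23859 are in GENCODE vM21 and 16541 have the same coordinates there. Chi-square per degree of freedom of replicate pairs ran from 11.6 to 73.5, so counting error is a small part of the spread between mice.

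Each comparison was fitted in R 4.3.3 with edgeR 4.0.16 on the libraries of its groups: genes kept by filterByExpr (minimum count 10, total 15), TMM scaling, quasi-likelihood fit and two-sided test, Benjamini-Hochberg adjusted p under 0.05. The test of the difference used the 20 libraries on the HFCF diet in 1 fit. Libraries of all groups were scaled together for CPM values and for principal components (log2 CPM, prior count 2). SE values are the log2 fold change divided by the square root of the F statistic. For low counts, ratios of count shares over the group were given with an exact 95% interval. Groups, tests, gene lists, the rule for named genes and all alternatives but 2 were chosen before the data were examined.

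The 27 lists were PPARγ-linked lipid uptake and lipid droplet, fatty acid and triglyceride synthesis, cholesterol synthesis, fatty acid oxidation and PPARα targets, bile acid synthesis and transport, methionine and one-carbon metabolism, glucose and fructose metabolism, xenobiotic metabolism, male-biased liver, female-biased liver, extracellular matrix and fibrosis, stellate cell and myofibroblast, Kupffer cell, recruited and lipid-associated macrophage, T/NK/B lymphocyte, neutrophil, cytokine/chemokine/adhesion, acute phase, interferon-stimulated, endothelial cell, cholangiocyte, hepatocyte, adipocyte, erythrocyte, cell cycle, endoplasmic reticulum stress and circadian clock. The bile acid and male-biased lists share Cyp7b1 and Slco1a1, and no other lists share a member. Camera (limma 3.58.1, preset correlation 0.01) tested each list against other genes, adjusted over the 27 lists. Camera with an estimated correlation and fry, which tests whether a list moves on balance in 1 direction, were alternatives.

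The text names, in each comparison, 21 fixed genes (Pparg, Cd36, Fabp4, Cidea, Cidec, Mogat1, Plin4, Fasn, Scd1, Sqle, Cpt1a, Pdk4, Fgf21, Cyp4a14, Cyp7a1, Bhmt, Col1a1, Timp1, Acta2, Ccl2 and Trem2). It also names the 5 highest and 5 lowest log2 fold changes among protein-coding genes that passed with at least 2 CPM in the higher group and no overlap between groups (no such condition for the difference), passing over gene models. Of the 3 members of each called list with the smallest adjusted p, and of the called members of the PPARγ-linked list, the text gives examples. Some genes that the rule names are not reported here. Correlations of fold changes between comparisons were computed across genes. For comparisons sharing HF_C, unchanged groups were simulated 20 times from negative binomial counts around HF_C means, and HF_C was split 2 and 3 in 20 ways.

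Alternatives were RLE scaling, no filter, DESeq2 1.42.0, a fit of all 24 libraries, a block for replicate numbers, a log2 fold change of at least 1, genes of at least 2 CPM, and each library left out in turn. Thinning to the lowest depth (1 binomial draw per library) and library totals without a scaling factor were added after seeing the data. Groups of libraries were also split in 100 ways (of 126 per comparison and 63504 for the difference, the real split included). Single libraries that stand apart were sought with Dixon's test, over 240 groups: library totals, mitochondrial and Alb shares, PC1 and the 21 fixed genes in all groups, and the genes with the largest changes in the groups compared. The code was tested on simulated data with 200 changed genes per comparison, of which 58 to 100% per fold were called, 3.31 to 6.73% of calls being false, and 1 unchanged list was called (in HF_C over LF_C). A covariance of 0.251 put into comparisons sharing HF_C was recovered as 0.247 and 0.248. Tables were joined and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No sample was left out, and the authors' signal, FPKM and tests were used only for checks and for the counts set beside the calls here.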

Results

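Whole liver RNA from 24 mice was sequenced, 1 library per mouse, and the reads of each gene were counted. The LF_C group (n = 4) held mice with the control genotype on the diet named LFCF, labelled low fat. The HF_C group (n = 5) held control mice after 34 weeks on the HFCF diet, which the series links to nonalcoholic steatohepatitis, fatty liver with inflammation. The HF_KO group (n = 5) was labelled as a knockout, in hepatocytes only, of PPARγ, a nuclear receptor activated by fatty acids. That knockout was induced after 24 of the 34 weeks and so lasted 10 weeks. The HF_TZD_C and HF_TZD_KO groups (n = 5 each) had the same genotypes and diet, with rosiglitazone maleate, a thiazolidinedione drug that activates PPARγ, added to the diet for the last 8 weeks.

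The libraries held from 19.5 to 28.7 M counted reads. In replicate order the totals were 22.6, 25.2, 25.5 and 24.7 M in LF_C and 28.7, 26.4, 26.7, 27.0 and 27.2 M in HF_C. The HF_KO libraries held 24.0, 23.3, 24.8, 26.8 and 25.9 M. The rosiglitazone libraries held 25.5, 23.4, 26.5, 27.3 and 21.3 M in HF_TZD_C and 22.0, 22.0, 19.5, 19.5 and 22.9 M in HF_TZD_KO, the group with the lowest mean (21.2 M). Alb, which encodes serum albumin, took 6.43 ± 0.717% of the reads (mean ± SD) in LF_C, 3.89 ± 0.269% in HF_C, 4.85 ± 0.352% in HF_KO, 3.40 ± 0.254% in HF_TZD_C and 6.69 ± 0.575% in HF_TZD_KO. The first principal component held 43% of the variance and separated the LF_C libraries (mean score -81.3) from HF_C (25.5) and HF_TZD_C (30.9). HF_TZD_KO replicate 5 lay at -57.7, nearer to LF_C than the other 4 libraries of its group, which lay between -4.26 and 17.6. Values below are mean scaled read counts (CPM) ± SD with n = 4 in LF_C and n = 5 in the other groups. Numbers after gene names in parentheses are log2 fold changes (first group over second, SE where given), and gene positions are on GRCm38. For every gene named as changed between groups, all 5 libraries of the first group lay beyond the mean of the second, apart from Pltp under the diet with 4 of 5. The libraries do not keep the strand, so reads of an overlapping expressed gene may enter the counts of Cidea, Plin4, Mogat1, Timp1, Tm7sf2, Fabp3, Acss2, Alas2, Pfkfb1, Pltp, Gbp3, Cideb, Ccna2, Shmt1, Acot3 and Ciart. Reads of near-identical genes (the Mup, Cyp2c, Saa and hemoglobin families) may be shared between their members.

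**Figure D1:**
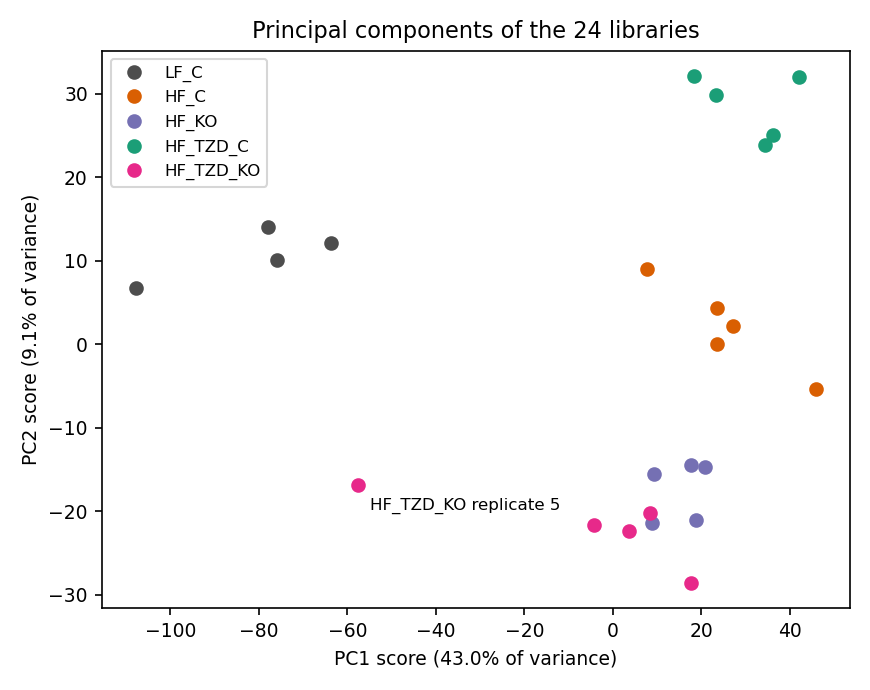
Principal component scores of the 24 libraries, PC1 (43% of variance) against PC2 (9.1%), each point a library coloured by group. HF_TZD_KO replicate 5 lies at -57.7 on PC1, between the other HF_TZD_KO libraries and LF_C.

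Pparg (ENSMUSG00000000440, chromosome 6, 115361221 to 115490401), which encodes PPARγ, is the gene named as knocked out. Its counts were not lower but higher in the libraries labelled knockout. In replicate order, Pparg stood at 16.3, 18.4, 16.7 and 10.0 CPM in LF_C and at 32.9, 33.6, 35.5, 28.3 and 31.8 CPM in HF_C. The HF_KO libraries held 60.6, 57.7, 70.2, 68.8 and 63.2 CPM and the HF_TZD_C libraries 24.6, 25.4, 30.6, 26.5 and 27.7 CPM. The HF_TZD_KO libraries held 56.0, 38.9, 62.0, 44.3 and 31.7 CPM. HF_KO exceeded HF_C by a log2 fold change of 0.99 (SE 0.08, adjusted p = 4.5e-05), and HF_TZD_KO exceeded HF_TZD_C by 0.79 (SE 0.16, adjusted p = 0.00421). In both comparisons all 5 libraries labelled knockout lay above all 5 controls. A gene-level count includes reads of exons outside a deletion and of liver cells other than hepatocytes, so it shows neither the presence nor the absence of the deletion. The groups are therefore called libraries labelled knockout, and each direction below follows the labels.

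**Figure D2:**
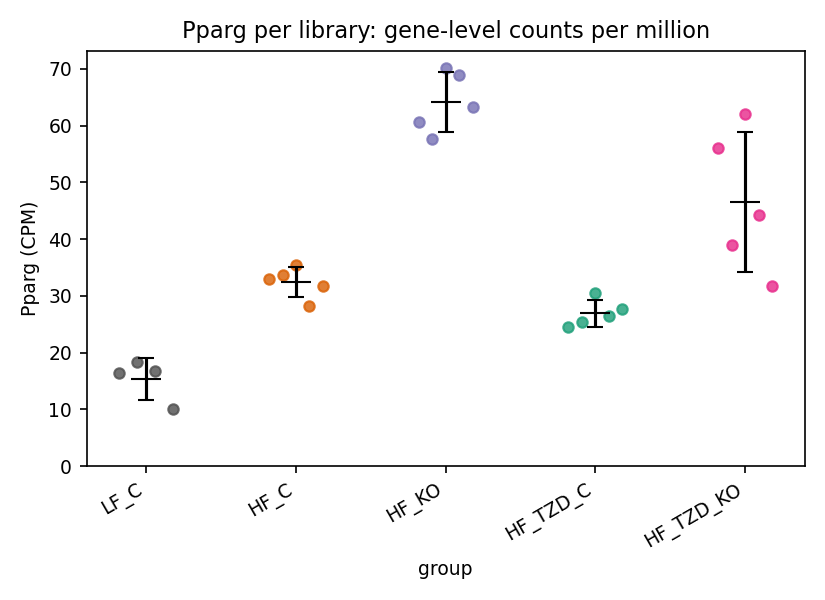
Pparg in CPM for each library by group, with the mean and SD as bars. The HF_KO libraries lie above the HF_C libraries, and the HF_TZD_KO libraries above the HF_TZD_C libraries.

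On the HFCF diet, livers of control mice held more transcripts of collagen, macrophage and bile duct genes than on the LFCF diet, and fewer of the genes of differentiated hepatocytes. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), a chain of type I collagen of scar tissue, averaged 184 ± 34.5 CPM in HF_C and 16.7 ± 3.90 CPM in LF_C (log2 fold change 3.45 (SE 0.19), adjusted p = 3.1e-06). Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147), a lipid-sensing receptor of macrophages, averaged 21.1 ± 6.11 CPM in HF_C and 1.34 ± 0.636 CPM in LF_C (log2 fold change 3.95 (SE 0.29), adjusted p = 4.6e-06). Slc10a1 (ENSMUSG00000021135, chromosome 12, 80953185 to 80968079), which takes bile acids up from the blood, averaged 227 ± 34.6 CPM in HF_C and 762 ± 131 CPM in LF_C (log2 fold change -1.76 (SE 0.13), adjusted p = 4.6e-06).

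The comparison of HF_C with LF_C asks what the HFCF diet changed in control mice. Of 14772 genes tested, 6003 passed an adjusted p of 0.05, 3168 of them higher and 2835 lower, and 2293 moved by at least 1 on the log2 scale (1936 up, 357 down). Scaled by library totals alone, the median of all genes was 0.24 in place of -0.03, and 5309 genes passed as higher and 886 as lower, so changes are given relative to the TMM-scaled genes. For each gene list, the members that passed, their number adjusted over the list alone and the median log2 fold change of all measured members stand with the adjusted p of camera at a preset correlation between genes. Where a call was lost with an estimated correlation, that p follows. The list calls that held with an estimated correlation were the PPARγ-linked list in both comparisons of libraries labelled knockout, under rosiglitazone in control mice and in the test of the difference, and the hepatocyte list in the last.

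In the extracellular matrix and fibrosis list 30 of 30 members rose (30 over the list alone, median 2.26, adjusted p = 8.0e-46, and 0.0871 with an estimated correlation), among them Col1a2 and Col6a3 (2.93 and 2.58, adjusted p at most 3.1e-06). Timp1, an inhibitor of matrix-degrading proteases, rose from 0.438 ± 0.238 to 6.39 ± 1.26 CPM (log2 fold change 3.81 (SE 0.32), adjusted p = 9.4e-06). Ccl2, which attracts monocytes, rose from 1.37 ± 0.543 to 7.96 ± 3.03 CPM (log2 fold change 2.51 (SE 0.32), adjusted p = 1.2e-04). In the recruited macrophage, cytokine and stellate cell lists, 21 of 22, 17 of 21 and 13 of 16 members rose (21, 19 and 15 over the list alone) and 1 in the stellate cell list fell. Their medians were 2.46, 1.40 and 0.86 (adjusted p from 1.0e-22 to 6.6e-07, and 0.0871 each with an estimated correlation). They included Lgals3, Itgax, Icam1 and Pdgfrb (2.59, 3.57, 1.14 and 1.77, adjusted p at most 3.5e-05), a lectin and an integrin of myeloid cells, an adhesion protein and a growth factor receptor of stellate cells. In the cholangiocyte, lymphocyte, neutrophil and cell cycle lists, 14 of 14, 13 of 22, 4 of 7 and 13 of 20 members rose (14, 13, 4 and 14 over the list alone). Their medians were 2.81, 1.24, 1.23 and 1.14 (adjusted p from 2.0e-14 to 0.0404, and from 0.124 to 0.386 with an estimated correlation). Among these were Cftr, Sox9, Cd8a, Ltb, Csf3r, Ccna2 and Mki67 (5.37, 2.28, 3.52, 2.22, 1.02, 1.25 and 1.53, adjusted p at most 4.2e-04), from bile duct to dividing cells. In the endoplasmic reticulum stress list, 8 of 18 members rose (8 over the list alone) and 1 fell. The median was 0.30 (adjusted p = 0.0454, and 0.514 with an estimated correlation). Members that passed included Atf3 and Trib3 (2.39 and 0.84, adjusted p at most 1.3e-04).

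Genes of hepatocyte function were among those that fell. In the hepatocyte, bile acid and cholesterol synthesis lists, 16 of 20, 10 of 21 and 14 of 24 members fell (17, 12 and 16 over the list alone) and 1 in the bile acid list rose. Their medians were -0.67, -0.39 and -0.70 (adjusted p from 9.9e-08 to 7.7e-04, and from 0.253 to 0.428 with an estimated correlation). LF_C 4 scored (mean log2 CPM of members against that of all libraries) 0.83 (others 0.26 to 0.33) in the hepatocyte and -0.32 (others 0.13 to 0.78) in the cholesterol synthesis list, and without it 17, 10 and 21 members fell (medians -0.52, -0.31 and -0.86). The members included Alb, Arg1, Ttr, Nr1h4, Tm7sf2 and Hsd17b7 (-0.99, -1.04, -0.90, -0.70, -1.62 and -1.19, adjusted p at most 7.4e-04), among them a urea cycle enzyme, a thyroid hormone carrier, the bile acid receptor and sterol enzymes. In the methionine, glucose, fatty acid oxidation and xenobiotic lists, 15 of 20, 13 of 20, 15 of 29 and 14 of 23 members fell (15, 16, 17 and 14 over the list alone), 1 in the methionine, 2 in the glucose, 1 in the fatty acid oxidation and 2 in the xenobiotic list rose. Their medians were -0.49, -0.45, -0.30 and -0.53 (adjusted p from 2.6e-05 to 0.00626, and from 0.238 to 0.386 with an estimated correlation). Examples were Gnmt, Ahcy, Slc2a5, Khk, Cyp4a14, Eci2, Nr1i3 and Cyp2c37 (-1.40, -1.07, -1.62, -0.80, -1.86, -0.71, -1.56 and -1.93, adjusted p at most 9.0e-04), the fructose transporter and ketohexokinase standing for the glucose and fructose list. In the male-biased, female-biased, circadian and erythrocyte lists, 10 of 18, 4 of 9, 14 of 18 and 4 of 7 members fell (10, 4, 14 and 4 over the list alone), 1 in the male-biased, 1 in the female-biased and 2 in the circadian list rose. Their medians were -1.22, -0.93, -0.71 and -0.80 (adjusted p from 1.8e-04 to 0.0404, and from 0.0871 to 0.386 with an estimated correlation). Called members included Mup3, Cyp2u1, Acot3, Tef, Hlf and Alas2 (-2.61, -1.58, -3.93, -0.88, -0.94 and -0.69, adjusted p at most 0.00371). The female-biased median was -0.18 without LF_C 2 and -0.61 without LF_C 3.

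Lipid genes were split. In the PPARγ-linked list of lipid uptake and lipid droplet genes 8 of 24 members rose and 8 fell (9 and 8 over the list alone, median 0.05, adjusted p = 0.459). Its risers included Fabp4, Cidea, Cidec, Lpl and Aqp7 (2.27, 3.69, 2.08, 3.41 and 6.34, adjusted p at most 0.00142), which bind, coat or hydrolyse lipid or carry glycerol. The genes that fell included G0s2, Acsl1, Lpin1, Retsat and Angptl4 (-1.16, -1.08, -1.65, -0.90 and -0.69, adjusted p at most 0.0143), Angptl4 at -0.46 without LF_C 4. Of the other fixed genes, Cpt1a, Pdk4, Acta2 and Sqle (-0.35, 0.90, 1.05 and -1.14, adjusted p at most 0.0470) passed. Camera did not call the fatty acid synthesis, Kupffer cell, acute phase, interferon, endothelial and adipocyte lists (adjusted p from 0.0598 to 0.784). Their medians were -0.33, -0.07, 0.15, 0.03, -0.03 and -0.01. In these lists 9 of 24, 10 of 15, 10 of 22, 7 of 22, 7 of 16 and 1 of 6 members passed (9, 11, 15, 7, 7 and 1 over the list alone). The adipocyte mean (0.93) differed in sign from its median, and the rotation test fry put the Kupffer list upwards.

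The fixed rule also named Sdcbp2 and Mmp7 (5.71 and 5.56, adjusted p at most 6.8e-05) as higher, and Cyp2c40, Hsd3b5, Cyp2c69, Grm8 and Cd163 (-7.17, -6.34, -5.76, -5.11 and -4.59, adjusted p at most 4.0e-04) as lower. Spire2, with 3 against 635 counts, had a ratio of count shares of 152 (95% interval 51.9 to 741). Fbn2, with 3 against 306 counts, had a ratio of count shares of 73.4 (95% interval 24.9 to 358). Such intervals cover counting error only, since PCR reads are not independent molecules. Mogat1 (0.53), Fasn (-0.02), Scd1 (0.19), Fgf21 (0.49), Cyp7a1 (-0.00) and Bhmt (-0.07) did not pass (adjusted p from 0.243 to 0.994). Cd36 (0.40, adjusted p = 0.0845), a fatty acid uptake receptor, and Plin4 (0.89, adjusted p = 0.0642), a droplet coat protein, passed without LF_C 2 (0.00331 and 5.1e-04). A single library stood apart within its group in HF_C 1 (Fabp4), LF_C 2 (Trem2 and Mmp7), LF_C 4 (Cyp2c69) and HF_C 5 (Cd163). Gene calls ended when 1 library was left out for Sqle (6 libraries, up to 0.124 without LF_C 3), Cpt1a (7 libraries, up to 0.0888 without LF_C 1), Pdk4 (7 libraries, up to 0.123 without LF_C 1), Acta2 (0.0527 without LF_C 1), Hba-a2 (0.0539 without LF_C 4), Pnpla2 (4 libraries, up to 0.0738 without HF_C 5), Slc27a1 (2 libraries, up to 0.0534 without LF_C 3), Pltp (7 libraries, up to 0.149 without LF_C 3), Hilpda (8 libraries, up to 0.0997 without LF_C 1) and Vldlr (4 libraries, up to 0.0711 without LF_C 3), each of the 9 libraries being among them. List calls ended for female-biased (3 libraries, up to 0.108 without HF_C 2), neutrophil (2 libraries, up to 0.122 without HF_C 2) and endoplasmic reticulum stress (3 libraries, up to 0.133 without HF_C 2). Calls began for fatty acid synthesis without LF_C 4 (0.00963), HF_C 2 (0.00585) or HF_C 5 (0.0436), acute phase without LF_C 4 (0.0202), interferon-stimulated without LF_C 3 (0.0117) and Kupffer cell without HF_C 5 (0.0397).

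Among mice on the HFCF diet, libraries labelled knockout held fewer transcripts of lipid droplet genes than controls. Plin4 (ENSMUSG00000002831, chromosome 17, 56100591 to 56109803) averaged 29.4 ± 9.03 CPM in HF_KO and 143 ± 30.9 CPM in HF_C (log2 fold change -2.27 (SE 0.19), adjusted p = 5.7e-05). Cidec (ENSMUSG00000030278, chromosome 6, 113424634 to 113435760), which fuses lipid droplets, averaged 83.5 ± 18.9 CPM in HF_KO and 172 ± 17.8 CPM in HF_C (log2 fold change -1.03 (SE 0.13), adjusted p = 0.00158). Cidea (ENSMUSG00000024526, chromosome 18, 67343564 to 67367794), a related droplet protein, averaged 3.57 ± 2.54 CPM in HF_KO and 31.7 ± 20.4 CPM in HF_C (log2 fold change -3.13 (SE 0.50), adjusted p = 0.00945). Cfd, the complement factor adipsin, fell from 9.31 ± 6.94 to 0.167 ± 0.159 CPM (log2 fold change -5.77 (SE 0.63), adjusted p = 5.2e-04). The direction follows the labels, and Pparg was higher in the same libraries.

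The comparison of HF_KO with HF_C asks what the labelled PPARγ knockout changed under the HFCF diet. Of 14844 genes tested, 152 passed an adjusted p of 0.05, 72 of them higher and 80 lower, and 37 moved by at least 1 on the log2 scale (15 up, 22 down). Scaled by library totals alone, the median of all genes was -0.04 in place of 0.00, and 56 genes passed as higher and 118 as lower. In the PPARγ-linked list 5 of 24 members fell (10 over the list alone, median -0.31, adjusted p = 3.6e-15, and 0.00368 with an estimated correlation), the others being Fitm1 and Fitm2 (-0.75 and -0.46, adjusted p at most 0.0347), membrane proteins needed for droplet formation. Fabp4, a fatty acid binding protein, stood at 24.5 ± 7.59 against 40.5 ± 8.96 CPM (log2 fold change -0.72 (SE 0.20), adjusted p = 0.130) and passed without HF_C 1 (0.0391) or HF_KO 5 (0.0231). In the methionine and xenobiotic lists, 4 of 20 and 2 of 23 members rose (7 and 8 over the list alone) and 1 in the xenobiotic list fell. Their medians were 0.15 and 0.30 (adjusted p from 3.2e-06 to 1.0e-04, and from 0.263 to 0.353 with an estimated correlation). They included Bhmt, Bhmt2, Gamt and Gsta2 (0.54, 0.38, 0.36 and 0.81, adjusted p at most 0.0264), enzymes of betaine, creatine and glutathione metabolism. In the endoplasmic reticulum stress, fatty acid oxidation, acute phase, cytokine and adipocyte lists, 1 of 18, 2 of 29, 3 of 22, 1 of 21 and 1 of 6 members fell (3, 6, 3, 1 and 1 over the list alone). Their medians were -0.24, -0.05, -0.06, -0.16 and -0.19 (adjusted p from 1.2e-07 to 0.0316, and from 0.263 to 0.556 with an estimated correlation). These were Trib3, Vnn1, Acaa1b, Orm3, Orm2, Saa3 and Cxcl1 (-0.63, -0.86, -0.68, -0.98, -0.51, -0.94 and -0.83, adjusted p at most 0.0494) and Cfd. Medians of called lists that moved over 1.5 times when 1 library was left out (value with all libraries first) were cytokine (-0.16, -0.08) without HF_KO 3, acute phase (-0.06, -0.03) without HF_C 3, endoplasmic reticulum stress (-0.24, -0.12) without HF_C 2, and fatty acid oxidation (-0.05, -0.12 to -0.03 without HF_C 3, HF_C 5, HF_KO 4 or HF_KO 5) and adipocyte (-0.19, -0.07 without HF_C 2, -0.31 without HF_C 4 and -0.13 without HF_KO 3).

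Outside the lists, Lrtm1, a membrane protein with leucine-rich repeats, rose from 0.977 ± 0.595 to 6.19 ± 2.79 CPM (log2 fold change 2.68 (SE 0.39), adjusted p = 0.00532). The largest changes by the fixed rule were also those of Aqp4, Clec2h, Cyp2c54 and Atp2b2 (1.40, 1.95, 1.61 and 1.40, adjusted p at most 0.0413). These rose, while Sdcbp2 and Mup17 (-4.06 and -4.37, adjusted p at most 0.0211) fell. Camera called the cholesterol synthesis, hepatocyte, interferon, erythrocyte, fatty acid synthesis, male-biased and female-biased lists upwards and the matrix and recruited macrophage lists downwards, with no member passing (camera adjusted p from 3.1e-21 to 0.0477, and from 0.263 to 0.672 with an estimated correlation). Medians of called lists that moved over 1.5 times were female-biased (0.41, 0.25) without HF_KO 1, matrix (-0.17, -0.11) and recruited macrophage (-0.23, -0.14) without HF_C 3, and fatty acid synthesis (0.15, 0.08 without HF_C 1 or HF_KO 4 and 0.30 without HF_C 2), male-biased (0.26, 0.10 to 0.62 without HF_C 1, HF_C 2, HF_C 3, HF_KO 3 or HF_KO 4), interferon (0.39, 0.61 without HF_C 2 and 0.21 without HF_KO 4) and hepatocyte (0.13, 0.08 without HF_C 3 and 0.06 without HF_KO 1). In the interferon list HF_KO 4 scored 1.20 (others 0.02 to 0.57) and HF_C 2 0.71 (others -0.07 to 0.10). The other 10 lists had camera adjusted p from 0.0652 to 0.927, and the median had another sign than the test in the stellate list (-0.08) and than the mean (-0.03) in the glucose list (0.03). Cd36 (-0.10), Mogat1 (-0.66), Fasn (0.04), Scd1 (0.05), Cpt1a (0.14), Pdk4 (-0.20), Fgf21 (0.02), Cyp7a1 (1.22), Col1a1 (-0.27), Timp1 (-0.56), Acta2 (-0.16), Ccl2 (-0.36) and Trem2 (-0.48) did not pass (adjusted p from 0.188 to 0.993). Uncalled lists passed without 1 library for bile acid without HF_KO 5 (0.0163), Kupffer downwards without HF_C 4 (0.0438) but upwards without HF_C 5 (0.0393), neutrophil (6 libraries, down to 0.00349 without HF_C 4), endothelial without HF_C 5 (0.00443) or HF_KO 3 (0.0248), cholangiocyte (5 libraries, down to 0.00133 without HF_C 2) and circadian without HF_KO 4 (0.0457) or HF_KO 5 (0.0163). Sqle (1.06, adjusted p = 0.126) passed without HF_C 2 (0.0156), and Cyp4a14 (-0.88, adjusted p = 0.0803) without HF_C 3 (0.0396) or HF_KO 1 (0.0267). A single library stood apart in HF_KO 4 (Fgf21), HF_KO 3 (Clec2h and Aqp4), HF_C 2 (Cyp2c54, Atp2b2 and Mup17) and HF_KO 1 (Cfd). The gene count was 64 without HF_C 4, 70 without HF_KO 3, 82 without HF_KO 2, 85 without HF_C 5 and 101 without HF_KO 1 and 90 in a fit of all 24 libraries, where the calls of Cidec (0.179), Cxcl1 (0.242) and Orm3 (0.103) and 8 other named genes ended. List calls ended for fatty acid oxidation (0.0764 without HF_KO 5), acute phase (0.0839 without HF_C 3), adipocyte (2 libraries, up to 0.0975 without HF_C 1), cytokine (4 libraries, up to 0.824 without HF_KO 3), male-biased (4 libraries, up to 0.428 without HF_C 1) and female-biased (6 libraries, up to 0.202 without HF_C 2). Gene calls ended when 1 library was left out for Bhmt (6 libraries, up to 0.0899 without HF_KO 3), Clec2h (7 libraries, up to 0.113 without HF_C 5), Cyp2c54 (3 libraries, up to 0.0606 without HF_C 4), Atp2b2 (8 libraries, up to 0.109 without HF_KO 3), Mup17 (3 libraries, up to 0.0774 without HF_KO 3), Vnn1 (0.0540 without HF_C 4), Acaa1b (7 libraries, up to 0.115 without HF_C 4), Gamt (3 libraries, up to 0.0590 without HF_C 5), Gsta2 (0.0694 without HF_KO 3), Orm2 (3 libraries, up to 0.0689 without HF_KO 3), Saa3 (9 libraries, up to 0.129 without HF_KO 3), Fitm1 (7 libraries, up to 0.0959 without HF_KO 2) and Fitm2 (5 libraries, up to 0.0950 without HF_C 4), each of the 10 libraries being among them.

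Under rosiglitazone, genes of fatty acid binding, uptake and storage rose in the livers of control mice on the HFCF diet. Fabp4 (ENSMUSG00000062515, chromosome 3, 10204347 to 10208576) averaged 542 ± 86.7 CPM in HF_TZD_C and 40.5 ± 8.96 CPM in HF_C (log2 fold change 3.74 (SE 0.17), adjusted p = 9.9e-08). Cd36 (ENSMUSG00000002944, chromosome 5, 17781690 to 17888959) averaged 541 ± 43.2 CPM in HF_TZD_C and 340.5 ± 23.4 CPM in HF_C (log2 fold change 0.67 (SE 0.07), adjusted p = 1.4e-04). Cfd rose from 9.31 ± 6.94 to 132 ± 42.5 CPM (log2 fold change 3.84 (SE 0.40), adjusted p = 1.2e-04).

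The comparison of HF_TZD_C with HF_C asks what rosiglitazone changed in control mice with the diet-induced disease. Of 14937 genes tested, 792 passed an adjusted p of 0.05, 402 of them higher and 390 lower, and 114 moved by at least 1 on the log2 scale (69 up, 45 down). In the PPARγ-linked list 11 of 24 members rose (11 higher and 1 lower over the list alone, median 0.35, adjusted p = 3.7e-20, and 0.00380 with an estimated correlation). Besides Fabp4 and Cd36, these were Vldlr, Lpl, Acsl1, Pnpla2, Gpd1, Plin4, Pltp, Fitm2 and Cidec (1.44, 0.94, 0.86, 0.77, 0.66, 0.62, 0.60, 0.59 and 0.44, adjusted p at most 0.0196). In the fatty acid oxidation and adipocyte lists, 10 of 29 and 1 of 6 members rose (12 and 2 over the list alone) and 1 in the fatty acid oxidation list fell. Their medians were 0.21 and 0.09 (adjusted p from 2.4e-08 to 0.0312, and from 0.435 to 0.610 with an estimated correlation). Members that passed included Vnn1 and Acaa1b (0.84 and 0.87, adjusted p at most 4.6e-04) and Cfd. In the acute phase, hepatocyte, methionine and endoplasmic reticulum stress lists, 5 of 22, 7 of 20, 4 of 20 and 1 of 18 members fell (9, 9, 9 and 2 over the list alone), 1 in the acute phase and 1 in the methionine list rose. Their medians were -0.20, -0.18, -0.18 and -0.23 (adjusted p from 3.5e-06 to 0.0388, and from 0.610 to 0.762 with an estimated correlation). They included Saa2, Saa1, Orm2, Ttr, Ass1, Pemt, Gamt, Bhmt2 and Herpud1 (-1.24, -1.08, -0.72, -0.45, -0.50, -0.37, -0.56, -0.33 and -0.32, adjusted p at most 0.0248), among them the serum amyloids and a urea cycle enzyme. Camera also called the endothelial and lymphocyte lists upwards and the cholesterol synthesis, cholangiocyte and interferon lists downwards, with no member passing (camera adjusted p from 3.7e-06 to 0.0357, and from 0.728 to 0.762 with an estimated correlation). Medians of called lists that moved over 1.5 times were cholesterol synthesis (-0.37, -0.17), interferon (-0.30, -0.12) and endoplasmic reticulum stress (-0.23, -0.12) without HF_C 2, cholangiocyte (-0.46, -0.24) without HF_C 3, and adipocyte (0.09, 0.01 to 0.25 without any 1 library other than HF_TZD_C 5 or HF_C 4). Otop1, with 2 against 281 counts, had a ratio of count shares of 154 (95% interval 42.2 to 1278). Mup9 (3.48, adjusted p = 3.3e-04) also rose and Rbm24, Apoa4, Slc22a29, Tinag and Gpr12 (-4.01, -2.35, -1.89, -1.86 and -1.59, adjusted p at most 0.00673) fell.

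Of the 52 members of the matrix and recruited macrophage lists, 1 passed under rosiglitazone. Col1a1 stood at 178 ± 52.1 and 184 ± 34.5 CPM (log2 fold change -0.05 (SE 0.17), adjusted p = 0.921), and the matrix list had a median of -0.03 (adjusted p = 0.933). Mogat1 (-0.13), Fasn (0.06), Scd1 (0.27), Cpt1a (-0.03), Pdk4 (0.29), Fgf21 (-0.19), Cyp4a14 (0.50), Cyp7a1 (0.67), Bhmt (-0.12), Timp1 (-0.14), Acta2 (0.15), Ccl2 (-0.16) and Trem2 (0.11) did not pass (adjusted p from 0.292 to 0.939). The other 15 lists had camera adjusted p from 0.0595 to 0.933. Uncalled lists passed without 1 library for male-biased without HF_C 1 (0.00429) or HF_C 3 (0.00817), Kupffer (3 libraries, down to 2.1e-04 without HF_C 5), recruited macrophage without HF_C 3 (0.00316), HF_TZD_C 3 (0.0353), HF_TZD_C 4 (0.0436) or HF_TZD_C 5 (0.0280), cytokine (7 libraries, down to 0.0112 without HF_TZD_C 1) and cell cycle (3 libraries, down to 0.0109 without HF_C 3). Pparg (-0.27, adjusted p = 0.0643) passed without HF_C 4 (0.0376) or HF_TZD_C 3 (0.0423), Cidea (0.58, adjusted p = 0.372) without HF_C 2 (0.0307), and Sqle (-0.85, adjusted p = 0.0692) without HF_C 1 (0.0223). A single library stood apart in HF_TZD_C 2 (Col1a1), HF_C 4 (Otop1), HF_TZD_C 4 (Rbm24), HF_TZD_C 1 (Slc22a29) and HF_C 1 (Gpr12). The gene count was 497 without HF_TZD_C 2 and 387 in a fit of all 24 libraries, where the calls of Cidec (0.577), Plin4 (0.335), Pltp (0.0939), Ass1 (0.150) and Herpud1 (0.168) were among those that ended. Calls ended without 1 library for Orm2 without HF_TZD_C 3 (0.0531) or HF_TZD_C 5 (0.0576), Ass1 without any 1 library other than HF_TZD_C 3, HF_TZD_C 4, HF_C 2 or HF_C 3 (0.0504 to 0.0710), Herpud1 without HF_C 5 (0.0583), HF_TZD_C 2 (0.0752), HF_TZD_C 3 (0.0630) or HF_TZD_C 5 (0.0721), and Pltp without HF_TZD_C 2 (0.0589). List calls ended for interferon (0.0614 without HF_C 2), adipocyte (0.0599 without HF_C 4), lymphocyte (4 libraries, up to 0.178 without HF_C 2) and endoplasmic reticulum stress (4 libraries, up to 0.380 without HF_C 2).

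**Figure D3:**
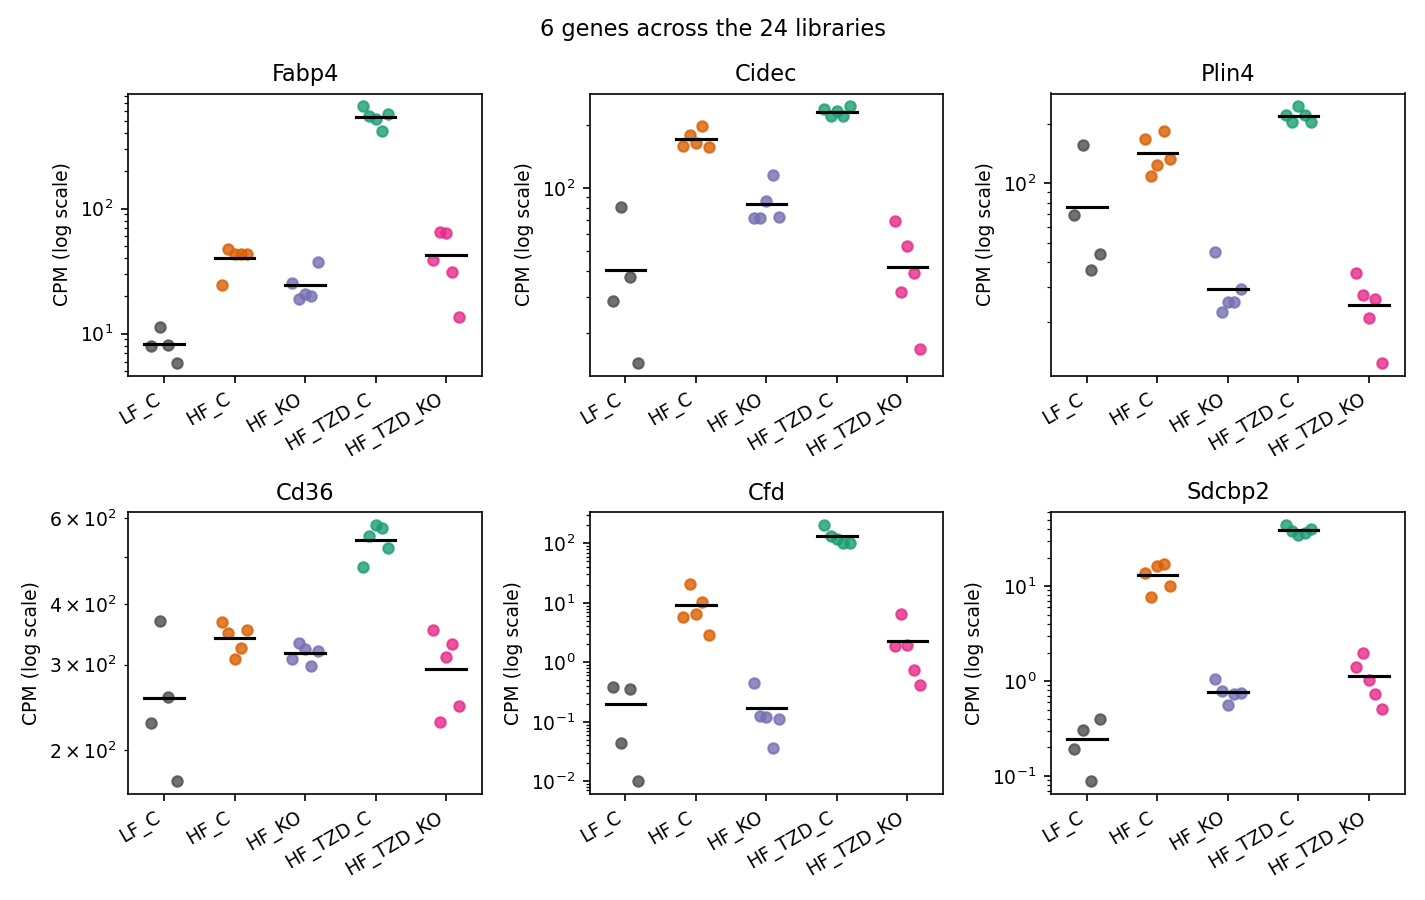
CPM on log axes of Fabp4, Cidec, Plin4, Cd36, Cfd and Sdcbp2 in each library by group, with the group mean as a bar and a count of 0 drawn at 0.01 CPM. Among the groups on the HFCF diet, HF_TZD_C holds the highest mean in each panel.

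In libraries labelled knockout, the lipid genes that rose under rosiglitazone in control mice did not pass the test. Fabp4 averaged 42.4 ± 21.9 CPM in HF_TZD_KO and 24.5 ± 7.59 CPM in HF_KO (log2 fold change 0.80 (SE 0.34), adjusted p = 0.286). Cd36 averaged 294 ± 53.6 CPM in HF_TZD_KO and 316 ± 13.5 CPM in HF_KO (log2 fold change -0.10 (SE 0.11), adjusted p = 0.745). Members of the interferon (5 of 22) and cell cycle (2 of 20) lists fell and a few hepatocyte genes rose, calls that each ended without any of 6 single libraries. Zbp1 (ENSMUSG00000027514, chromosome 2, 173206612 to 173218923), a nucleic acid sensor, averaged 11.9 ± 2.65 CPM in HF_TZD_KO and 28.97 ± 8.54 CPM in HF_KO (log2 fold change -1.27 (SE 0.20), adjusted p = 0.0365).

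The comparison of HF_TZD_KO with HF_KO asks what rosiglitazone changed in libraries labelled knockout. Of 14559 genes tested, 107 passed an adjusted p of 0.05, 62 of them higher and 45 lower, and 31 moved by at least 1 on the log2 scale (14 up, 17 down). Scaled by library totals alone, the median of all genes was -0.11 in place of 0.00, and 51 genes passed as higher and 169 as lower. In the interferon, cell cycle, matrix and cytokine lists, 5 of 22, 2 of 20, 1 of 30 and 1 of 21 members fell (22, 13, 9 and 5 over the list alone). Their medians were -0.99, -0.71, -0.39 and -0.37 (adjusted p from 3.7e-31 to 1.3e-04, and from 0.149 to 0.395 with an estimated correlation). Without HF_TZD_KO 5, lowest of its group in all 4, the medians were -0.93, -0.53, -0.18 and -0.26 and 4, 3, 3 and 1 members fell. Without HF_KO 4, which scored 1.20 in the interferon list (others 0.02 to 0.57), the medians were -0.78, -0.65, -0.43 and -0.34 and no member passed (adjusted p of the lists at most 8.5e-04 in both). The members were led by Zbp1, Gbp3, Ccnb2, Ccnb1, Mmp13 and Tlr2 (-1.27, -1.15, -1.56, -1.36, -1.42 and -0.59, adjusted p at most 0.0453), among them cyclins and a collagenase. In the hepatocyte, fatty acid synthesis, cholesterol synthesis, methionine and glucose lists, 2 of 20, 2 of 24, 1 of 24, 2 of 20 and 2 of 20 members rose (14, 5, 6, 10 and 2 over the list alone). Their medians were 0.38, 0.24, 0.50, 0.29 and 0.18 (adjusted p from 9.1e-16 to 1.8e-04, and from 0.149 to 0.355 with an estimated correlation). The members were Cps1, Arg1, Pnpla3, Thrsp, Stard4, Ahcy, Gnmt, Pfkfb1 and Foxo1 (0.92, 0.57, 1.39, 1.22, 0.57, 0.68, 0.62, 0.90 and 0.36, adjusted p at most 0.0488), the first pair being urea cycle enzymes. In the recruited macrophage list, called downwards, 1 of 22 members rose (1 higher and 1 lower over the list alone, median -0.36, adjusted p = 3.5e-04, and 0.542 with an estimated correlation). Camera also called the neutrophil, circadian and bile acid lists upwards and the cholangiocyte list downwards, with no member passing (camera adjusted p from 1.1e-08 to 0.0130, and from 0.149 to 0.541 with an estimated correlation). Medians of called lists that moved over 1.5 times were cholesterol synthesis (0.50, 0.25) without HF_TZD_KO 4 and bile acid (0.33, 0.11), recruited macrophage (-0.36, -0.20) and cholangiocyte (-0.24, -0.12) without HF_TZD_KO 5.

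The largest rises by the fixed rule included Cyp2c40, Hamp2, Hamp and Acpp (2.50, 2.03, 1.41 and 1.22, adjusted p at most 0.0373). The largest falls were those of Gsta1, Abcc12 and Gbp6 (-2.19, -1.76 and -1.40, adjusted p at most 0.0365). The other 13 lists had camera adjusted p from 0.0540 to 0.903, among them the PPARγ-linked list (median and mean 0.03 and -0.04). Uncalled lists passed without 1 library for fatty acid oxidation (4 libraries, down to 3.0e-04 without HF_KO 5), male-biased (4 libraries, down to 0.00199 without HF_TZD_KO 4), stellate cell without HF_TZD_KO 5 (4.0e-04), Kupffer without HF_TZD_KO 4 (0.00889), lymphocyte (3 libraries, down to 0.00941 without HF_KO 3) and endothelial (3 libraries, down to 0.0156 without HF_KO 3). Pparg (-0.45), Cidea (0.25), Mogat1 (-1.45), Plin4 (-0.26), Fasn (0.66), Scd1 (0.29), Sqle (0.51), Cpt1a (-0.03), Pdk4 (-0.84), Fgf21 (-0.56), Cyp4a14 (0.38), Cyp7a1 (0.55), Bhmt (0.33), Timp1 (-0.77), Acta2 (0.05), Ccl2 (-0.58) and Trem2 (-0.13) did not pass (adjusted p from 0.0966 to 0.954). Cidec (-0.99, adjusted p = 0.123) passed without HF_TZD_KO 1 (0.0446), and Col1a1 (-0.85, adjusted p = 0.136) without HF_TZD_KO 5 (0.0408). EdgeR called 0 genes without HF_KO 2, HF_KO 3, HF_KO 4, HF_KO 5, HF_TZD_KO 2 or HF_TZD_KO 4. Without any of these, the 107 genes, picked on the same libraries, had adjusted p of 0.0540 to 0.134. Then 1791 to 2481 genes had an unadjusted p under 0.05 (2232 with all libraries). DESeq2 called 649 with all libraries. The count was 14 without HF_TZD_KO 3, 159 without HF_TZD_KO 5 and 223 without HF_TZD_KO 1, 201 without a filter and 440 in a fit of all 24 libraries, 20 named calls also ended without HF_TZD_KO 1, HF_TZD_KO 3, HF_TZD_KO 5 or HF_KO 1 (0.0504 to 0.102). List calls ended for bile acid (2 libraries, up to 0.115 without HF_TZD_KO 5) and cholangiocyte (0.115 without HF_TZD_KO 5).

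Under rosiglitazone, libraries labelled knockout held fewer transcripts of PPARγ-linked lipid genes than controls, and more of the genes of cholesterol synthesis and hepatocyte identity. Fabp4 averaged 42.4 ± 21.9 CPM in HF_TZD_KO and 542 ± 86.7 CPM in HF_TZD_C (log2 fold change -3.67 (SE 0.35), adjusted p = 2.3e-05). Plin4 averaged 24.4 ± 8.46 CPM in HF_TZD_KO and 219 ± 16.5 CPM in HF_TZD_C (log2 fold change -3.16 (SE 0.21), adjusted p = 2.1e-06). Vnn1 (ENSMUSG00000037440, chromosome 10, 23894688 to 23905343), a pantetheinase controlled by PPARα, averaged 66.6 ± 9.15 CPM in HF_TZD_KO and 301 ± 6.55 CPM in HF_TZD_C (log2 fold change -2.17 (SE 0.09), adjusted p = 9.7e-08). Sqle (ENSMUSG00000022351, chromosome 15, 59315077 to 59331192), the squalene epoxidase of sterol synthesis, averaged 76.7 ± 36.8 CPM in HF_TZD_KO and 14.5 ± 1.96 CPM in HF_TZD_C (log2 fold change 2.41 (SE 0.28), adjusted p = 1.1e-04).

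The comparison of HF_TZD_KO with HF_TZD_C asks what the labelled PPARγ knockout changed in treated mice. Of 14602 genes tested, 2387 passed an adjusted p of 0.05, 1246 of them higher and 1141 lower, and 524 moved by at least 1 on the log2 scale (253 up, 271 down). Scaled by library totals alone, the median of all genes was -0.16 in place of 0.00, and 740 genes passed as higher and 2916 as lower. The direction follows the labels, and Pparg was higher in the libraries labelled knockout. In the PPARγ-linked list 2 of 24 members rose and 13 fell (2 and 17 over the list alone, median -0.92, adjusted p = 1.6e-19, and 0.00496 with an estimated correlation). HF_TZD_KO 5 scored -0.90 (others -0.29 to -0.21) there, and without it 2 rose and 16 fell (median -0.90, adjusted p = 1.7e-25). Besides Fabp4 and Plin4, the fall took in Cidea, Cidec, Mogat1, Vldlr, Lpl, Gpd1, Fitm1, Fitm2, Pnpla2, Cd36 and Acsl1 (-3.47, -2.47, -1.99, -1.70, -1.47, -1.35, -1.19, -1.04, -0.96, -0.88 and -0.48, adjusted p at most 0.0344). Cideb and Lpin1 (0.77 and 1.56, adjusted p at most 0.0125) rose, Lpin1 by 1.02 without HF_TZD_KO 4. In the fatty acid oxidation list, 13 of 29 members fell (15 over the list alone) and 1 rose. The median was -0.35 (adjusted p = 4.3e-14, and 0.151 with an estimated correlation). Called members included Acaa1b, Eci1 and Pdk4 (-1.82, -0.83 and -1.34, adjusted p at most 0.00397). In the cholesterol synthesis, fatty acid synthesis, hepatocyte, methionine and bile acid lists, 23 of 24, 12 of 24, 18 of 20, 15 of 20 and 9 of 21 members rose (24, 13, 19, 16 and 10 over the list alone), 1 in the fatty acid synthesis, 2 in the methionine and 3 in the bile acid list fell. Their medians were 1.45, 0.39, 0.75, 0.66 and 0.29 (adjusted p from 6.8e-31 to 0.0292, and from 0.0978 to 0.539 with an estimated correlation). They included Tm7sf2, Dhcr7, Acss2, Fads1, Ahsg, Bhmt, Dmgdh, Cyp7a1 and Slc10a1 (1.67, 1.44, 2.12, 0.78, 0.94, 0.98, 1.02, 1.09 and 1.28, adjusted p at most 0.00376), Cyp7a1 being the rate-limiting enzyme of bile acid synthesis.

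Genes of matrix and immune cells were among those that fell. In the matrix, recruited macrophage and cytokine lists, 12 of 30, 8 of 22 and 9 of 21 members fell (18, 13 and 14 over the list alone). Their medians were -0.51, -0.72 and -0.65 (adjusted p from 1.1e-06 to 1.9e-05, and from 0.233 to 0.454 with an estimated correlation). They included Col1a1, Col3a1, Timp1, Ccr2, Ly6c2, Ccl2 and Ccl4 (-1.09, -1.19, -1.20, -1.21, -1.39, -0.79 and -1.35, adjusted p at most 0.0206), collagens, a protease inhibitor and genes of monocytes and their attraction. HF_TZD_KO 5 scored -1.11 (others -0.02 to 0.23) in the matrix and -1.10 (others -0.19 to 0.44) in the recruited macrophage list. The gap to the nearest other library was over 0.71 of the group's range in the PPARγ-linked (0.884), matrix (0.816), cell cycle (0.756) and xenobiotic (0.735) lists. Without it the medians of the matrix and recruited macrophage lists were -0.38 (adjusted p = 1.8e-05) and -0.51 (adjusted p = 7.2e-05), and that of the xenobiotic list 0.16. In the interferon, cell cycle, endothelial and lymphocyte lists, 7 of 22, 7 of 20, 4 of 16 and 2 of 22 members fell (11, 11, 5 and 2 over the list alone) and 1 in the interferon list rose. Their medians were -0.40, -0.62, -0.34 and -0.68 (adjusted p from 1.4e-04 to 0.00388, and from 0.448 to 0.487 with an estimated correlation). Members that passed included Ifi27l2b, Zbp1, Mcm5, Mcm2, Fcgr2b, Pecam1, Tek, Ms4a1 and Ptprc (-1.10, -0.94, -0.68, -0.69, -0.60, -0.52, -0.45, -1.51 and -0.80, adjusted p at most 0.0343). In the neutrophil, glucose, xenobiotic, male-biased, circadian, acute phase and erythrocyte lists, 7 of 10, 7 of 20, 9 of 23, 8 of 17, 6 of 18, 7 of 22 and 1 of 7 members rose (7, 9, 10, 10, 6, 9 and 1 over the list alone), 1 in the neutrophil, 2 in the glucose, 2 in the xenobiotic and 1 in the acute phase list fell. Their medians were 1.69, 0.28, 0.31, 0.92, 0.35, 0.37 and 0.42 (adjusted p from 4.7e-05 to 0.0491, and from 0.212 to 0.562 with an estimated correlation). Called members included Camp, Ltf, Gckr, Cyp2c54, Slco1a1, Susd4, Per2, Itih3, Saa4 and Alas2 (4.31, 3.56, 0.93, 3.24, 4.49, 1.81, 0.68, 0.62, 0.70 and 1.20, adjusted p at most 0.0176). The erythrocyte median was 0.12 without HF_TZD_KO 2. The other 6 lists had camera adjusted p from 0.129 to 0.781. Uncalled lists passed without 1 library for Kupffer without HF_TZD_KO 4 (0.00777) and adipocyte without HF_TZD_KO 2 (0.0118).

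The largest rises by the fixed rule also included Lrtm1, Chrna4 and Rbm24 (4.53, 4.03 and 3.82, adjusted p at most 1.9e-04). The largest falls were those of Cfd, Fabp3, Sdcbp2, Scnn1g and Mup17 (-5.80, -5.55, -5.05, -4.45 and -4.40, adjusted p at most 8.6e-04). Scd1 (0.05), Cpt1a (0.12), Fgf21 (-0.35), Cyp4a14 (-1.004) and Acta2 (-0.28) did not pass (adjusted p from 0.151 to 0.877). Fasn (0.64, adjusted p = 0.0595) passed without HF_TZD_KO 1 (0.0321), HF_TZD_KO 2 (0.0368) or HF_TZD_KO 5 (0.0401), and Trem2 (-0.73, adjusted p = 0.149) without HF_TZD_KO 2 (0.0277). A single library stood apart in HF_TZD_KO 2 (Cfd), HF_TZD_KO 3 (Mup17) and HF_TZD_KO 5 (Rbm24). The gene count was 1569 without HF_TZD_C 2 and 2390 without HF_TZD_KO 5, the library nearest to LF_C. Gene calls ended for Col1a1 without HF_TZD_C 2 (0.0604), Ptprc without HF_TZD_C 2 (0.0515), Saa4 without HF_TZD_C 5 (0.0503), Pecam1 without HF_TZD_C 2 (0.0879), HF_TZD_C 4 (0.0673), HF_TZD_C 5 (0.0773) or HF_TZD_KO 2 (0.0551), Tek without any 1 library other than HF_TZD_KO 3, HF_TZD_KO 4 or HF_TZD_C 1 (0.0506 to 0.0844), and Acsl1 without any 1 library other than HF_TZD_KO 3, HF_TZD_KO 5, HF_TZD_C 1 or HF_TZD_C 4 (0.0608 to 0.0826). List calls ended for male-biased (0.0702 without HF_TZD_KO 3), bile acid (2 libraries, up to 0.160 without HF_TZD_KO 5), xenobiotic (0.0574 without HF_TZD_C 5), acute phase (5 libraries, up to 0.181 without HF_TZD_KO 1) and erythrocyte (6 libraries, up to 0.112 without HF_TZD_KO 2).

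**Figure D4:**
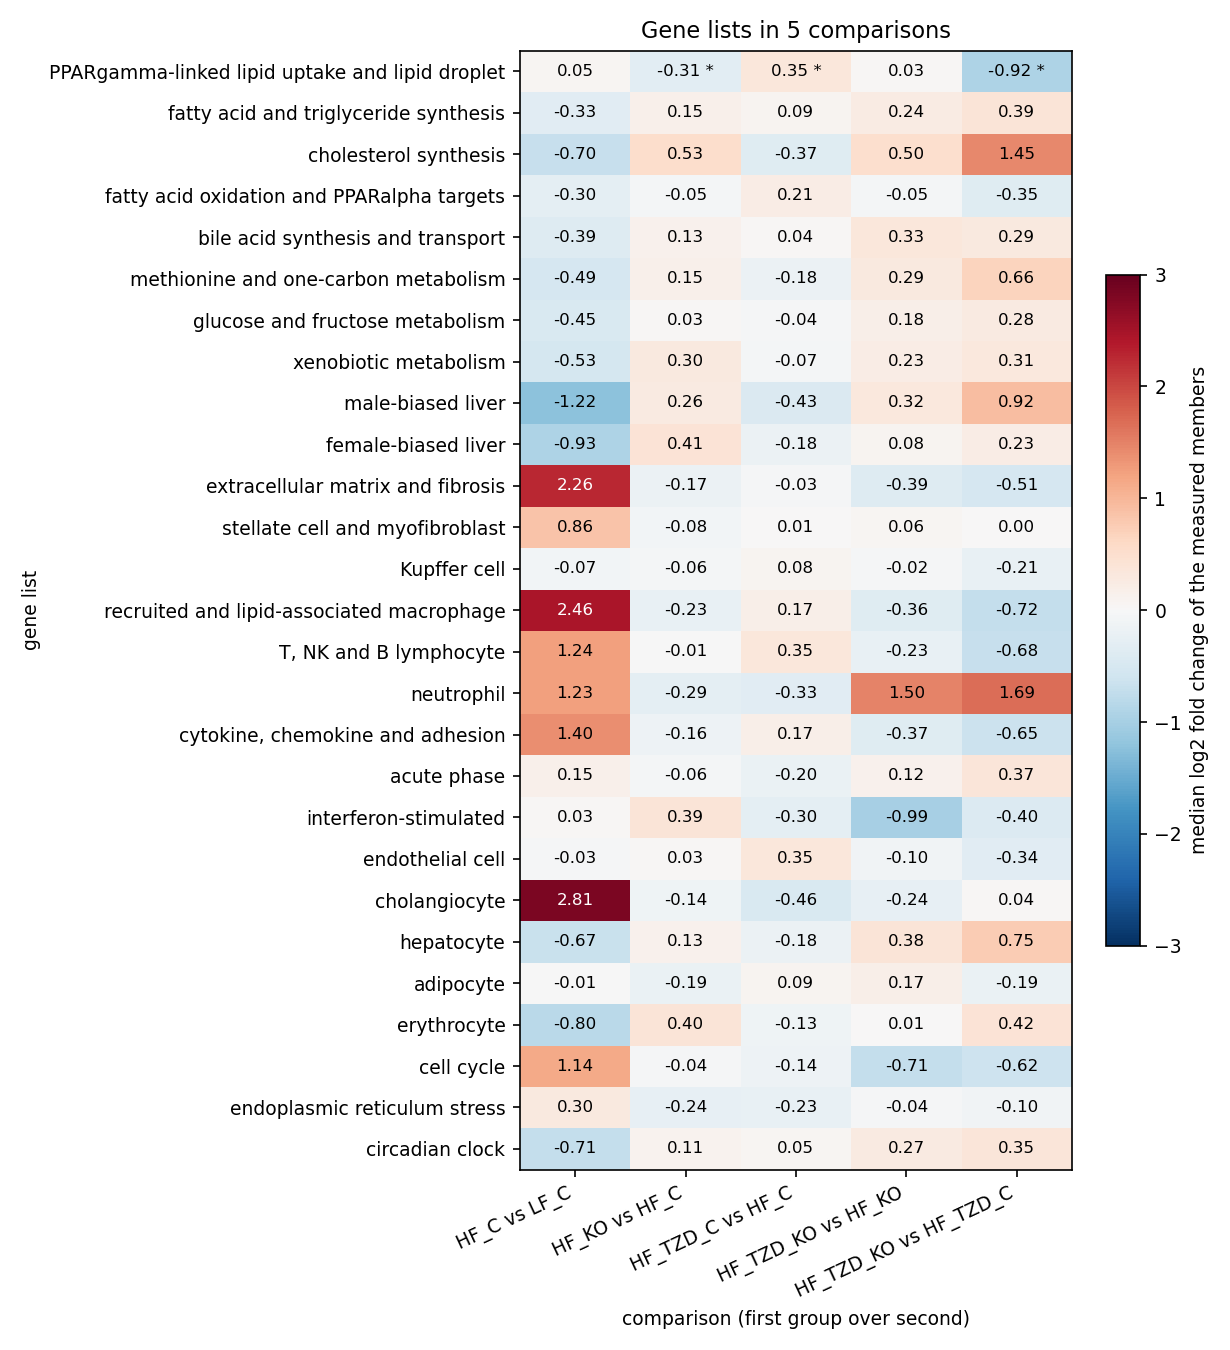
Median log2 fold change of the measured members of each of the 27 gene lists in 5 comparisons, first group over second, with an asterisk where camera passed with an estimated correlation. The asterisks stand at the PPARγ-linked list in 3 comparisons, at -0.31, 0.35 and -0.92.

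The rosiglitazone response of lipid genes differed between the genotypes as labelled. Fabp4 averaged 40.5 ± 8.96 CPM in HF_C, 542 ± 86.7 in HF_TZD_C, 24.5 ± 7.59 in HF_KO and 42.4 ± 21.9 in HF_TZD_KO (difference -2.95 (SE 0.41), adjusted p = 0.00134). Vldlr (ENSMUSG00000024924, chromosome 19, 27216484 to 27254231), a lipoprotein receptor, averaged 11.4 ± 3.20 CPM in HF_C, 31.0 ± 3.03 in HF_TZD_C, 10.3 ± 2.03 in HF_KO and 9.54 ± 2.68 in HF_TZD_KO (difference -1.54 (SE 0.27), adjusted p = 0.00302).

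The test of the difference takes the rosiglitazone log2 effect in libraries labelled knockout minus that in controls, over the 20 libraries on the HFCF diet, and asks whether the drug acted alike in both. Of 15365 genes tested, 376 passed an adjusted p of 0.05, 239 of them higher and 137 lower, and 90 moved by at least 1 on the log2 scale (44 up, 46 down). Scaled by library totals alone, the median of all genes was -0.12 in place of 0.01, and 163 genes passed as higher and 387 as lower. In the PPARγ-linked list 7 of 24 members had a negative difference (11 lower and 1 higher over the list alone, median -0.49, adjusted p = 1.2e-08, and 0.0166 with an estimated correlation). Among these were Cd36, Cidec, Fitm2, Pnpla2 and Gpd1 (-0.77, -1.43, -0.57, -0.63 and -0.71, adjusted p at most 0.0481). In the hepatocyte list 10 of 20 members had a positive difference (17 over the list alone, median 0.61, adjusted p = 1.7e-22, and 0.0218 with an estimated correlation). Called members included Ahsg and Ass1 (0.76 and 0.98, adjusted p at most 0.00468). In the fatty acid oxidation, interferon and cytokine lists, 7 of 29, 2 of 22 and 1 of 21 members had a negative difference (10, 12 and 2 over the list alone). Their medians were -0.25, -0.77 and -0.52 (adjusted p from 3.0e-11 to 2.3e-05, and 0.271 each with an estimated correlation). Members that passed included Vnn1, Acaa1b, Acot2, Zbp1, Ifi27l2b and Tlr2 (-1.30, -1.13, -1.13, -1.43, -0.86 and -0.76, adjusted p at most 0.0418). In the methionine, neutrophil, cholesterol synthesis, fatty acid synthesis, glucose and male-biased lists, 7 of 20, 2 of 10, 1 of 24, 1 of 24, 1 of 20 and 1 of 18 members had a positive difference (12, 5, 21, 5, 4 and 2 over the list alone). Their medians were 0.44, 2.01, 0.91, 0.32, 0.25 and 0.72 (adjusted p from 2.4e-14 to 0.0237, and from 0.0770 to 0.652 with an estimated correlation). Called members included Pemt, Bhmt2, Gnmt, Ltf, Mmp8, Insig1, Acss2, Gckr and Slco1a1 (0.70, 0.55, 1.01, 5.05, 2.78, 1.09, 1.28, 0.76 and 3.90, adjusted p at most 0.0483). Camera also called the acute phase and circadian lists upwards and the matrix, cell cycle, endothelial, recruited macrophage, lymphocyte and Kupffer lists downwards, with no member passing (camera adjusted p from 8.6e-06 to 0.0436, and from 0.275 to 0.594 with an estimated correlation). Medians of called lists that moved over 1.5 times were fatty acid synthesis (0.32, 0.18) and neutrophil (2.01, 1.16) without HF_C 2, fatty acid oxidation (-0.25, -0.14) without HF_C 3, matrix (-0.30, -0.18) and recruited macrophage (-0.45, -0.27) without HF_TZD_KO 5, and male-biased (0.72, 0.29 without HF_C 2, 0.46 without HF_TZD_KO 5 and 0.37 without HF_TZD_KO 3) and Kupffer (-0.25, -0.43 to -0.10 without HF_C 2, HF_C 4, HF_C 5, HF_TZD_C 1, HF_TZD_KO 2, HF_TZD_KO 4 or HF_TZD_KO 5). Ltf came to 3.30 without HF_C 2.

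The largest differences by the fixed rule also included Rbm24, Chrna4 and Avpr1a (2.96, 2.65 and 1.86, adjusted p at most 0.0418) among the positive ones, and Fabp3, Kcnk3, Ubd and Themis (-3.73, -2.70, -2.11 and -2.09, adjusted p at most 0.0162) among the negative. The other 8 lists had camera adjusted p from 0.0604 to 0.807. Uncalled lists passed without 1 library for bile acid (10 libraries, down to 0.0119 without HF_TZD_KO 1), stellate cell without HF_TZD_KO 5 (0.0357), cholangiocyte (3 libraries, down to 0.0321 without HF_TZD_KO 5) and endoplasmic reticulum stress without HF_KO 5 (0.0171) or HF_TZD_C 4 (0.0305). Median and mean had different signs in the Kupffer list (-0.25 and 0.07). Pparg (-0.19), Cidea (-0.33), Mogat1 (-1.32), Fasn (0.61), Scd1 (0.02), Sqle (1.36), Cpt1a (-0.01), Fgf21 (-0.37), Cyp4a14 (-0.11), Cyp7a1 (-0.11), Bhmt (0.45), Col1a1 (-0.81), Timp1 (-0.63), Acta2 (-0.10), Ccl2 (-0.41) and Trem2 (-0.25) did not pass (adjusted p from 0.109 to 0.987). Plin4 (-0.88, adjusted p = 0.117) passed without HF_TZD_KO 1 (0.0437), and Pdk4 (-1.13, adjusted p = 0.0830) without HF_TZD_KO 4 (0.0254). A single library stood apart in HF_C 2 (Slco1a1 and Ltf) and HF_KO 1 (Ltf). The gene count was 191 without HF_TZD_C 2, 205 without HF_KO 2, 233 without HF_C 5, 241 without HF_TZD_C 5 and 337 without HF_TZD_KO 5. List calls ended for circadian (3 libraries, up to 0.0719 without HF_KO 5), male-biased (4 libraries, up to 0.366 without HF_TZD_KO 3) and Kupffer (10 libraries, up to 0.214 without HF_C 4). Gene calls ended for Ltf (14 libraries, up to 0.179 without HF_C 2), Slco1a1 (13 libraries, up to 0.105 without HF_C 2), Chrna4 (12 libraries, up to 0.0888 without HF_TZD_C 2), Acss2 (15 libraries, up to 0.102 without HF_TZD_C 2), Insig1 (15 libraries, up to 0.0910 without HF_TZD_C 2), Mmp8 (13 libraries, up to 0.0816 without HF_TZD_C 2), Tlr2 (9 libraries, up to 0.0677 without HF_KO 2), Ifi27l2b (14 libraries, up to 0.0806 without HF_C 1) and Gpd1 (16 libraries, up to 0.0980 without HF_TZD_C 2), each of the 20 libraries other than HF_TZD_KO 1 being among them.

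**Figure D5:**
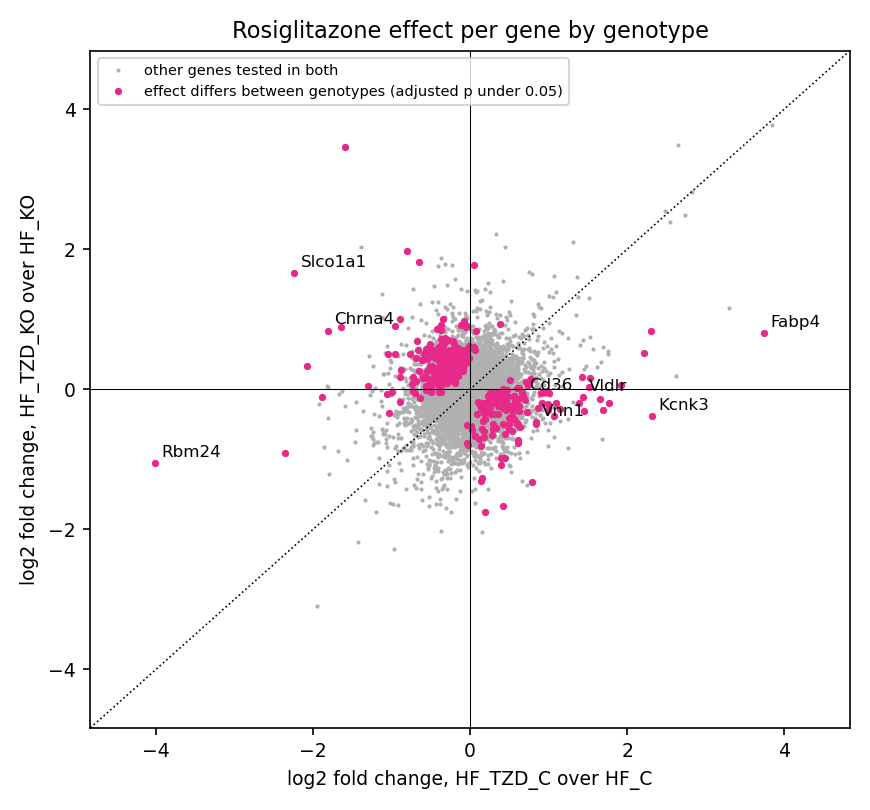
Log2 fold change of each gene under rosiglitazone in control libraries (x) against libraries labelled knockout (y), with genes whose effects differ at an adjusted p under 0.05 in colour and the line of equal effects dotted. Fabp4 stands at 3.74 on the x axis and 0.80 on the y axis.

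Effects of the labelled knockout with and without rosiglitazone were positively correlated. Plin4, Cidea, Cidec, Cfd and Sdcbp2 fell and Lrtm1 rose in both comparisons of libraries labelled knockout with controls. The log2 fold changes of HF_KO over HF_C and HF_TZD_KO over HF_TZD_C share no library. Across 14469 genes they had Pearson r = 0.543 (jackknife SE 0.0861 over libraries) and Spearman rho = 0.417. With DESeq2, whose gene set may differ, r was 0.168. Of the genes called in both, 62 were higher in both (6.16 if independent), 73 lower in both (6.22 if independent) and no gene was called in opposite directions by edgeR. The rosiglitazone effects in the genotypes as labelled, also without a shared library, had r = 0.146 (SE 0.106) and rho = 0.0549 across 14446 genes, with 10 genes higher in both (1.61 if independent), 13 lower in both (1.21 if independent), and 1 and 4 opposite. Genes are not independent replicates, so no p is given for these correlations.

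Genes changed by the diet were set against the drug and the labelled knockout, comparisons that share the HF_C libraries with opposite sign. Col1a1 and Trem2, for example, rose with the diet and did not pass in either. Diet and rosiglitazone effects had r = -0.0562 (SE 0.193) and rho = 0.0150 across 14641 genes, with 203 genes called in the same and 232 in opposite directions. If independent, these counts would be 83.7 and 74.3 for higher or lower in both, where 71 and 132 were seen, and 84.3 and 73.8 for higher then lower or lower then higher, where 91 and 141 were seen. Unchanged groups simulated around HF_C means gave a covariance of -0.0187, against -0.0150 observed, a difference of 0.00371 (mean r -0.471 without effects, not comparable). With the HF_C libraries split between the comparisons, r averaged 0.0300 over 20 splits (-0.196 to 0.246). The correlation was positive without HF_C 3 (0.0482) or HF_TZD_C 3 (0.0164) and over genes of at least 2 CPM (0.0431). Diet and labelled knockout effects had r = -0.380 (SE 0.173) and rho = -0.407 across 14625 genes, with 4 and 8 genes higher or lower in both (15.4 and 15.3 if independent), and 38 and 51 opposite (17.3 and 13.6 if independent). Unchanged groups simulated around HF_C means gave a covariance of -0.0194, against -0.0883 observed, a difference of -0.0689 (mean r -0.472, not comparable). With the HF_C libraries split between the comparisons, r averaged -0.236 over 20 splits (-0.456 to 0.0298).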

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

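The tests on Pparg, those on the hepatocyte and macrophage lists, and for HF_TZD_KO replicate 5 those on genes called under the labelled knockout and not under the diet and on cholangiocyte genes were chosen after the result was seen, while the others were written before. SE values in these tests are over genes, not mice.

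The effect of rosiglitazone differed between libraries labelled knockout and controls by a test of the difference in 376 genes and in the PPARγ-linked (-0.49) and hepatocyte (0.61) lists, the lists that passed with an estimated correlation. Among named genes, the difference was negative in Cd36 (-0.77), Fabp4 (-2.95), Cidec (-1.43), Fabp3 (-3.73), Kcnk3 (-2.70), Ubd (-2.11), Themis (-2.09), Vldlr (-1.54), Vnn1 (-1.30), Acaa1b (-1.13), Acot2 (-1.13), Tlr2 (-0.76), Zbp1 (-1.43), Ifi27l2b (-0.86), Fitm2 (-0.57), Pnpla2 (-0.63) and Gpd1 (-0.71). It was positive in Ltf (5.05), Slco1a1 (3.90), Rbm24 (2.96), Chrna4 (2.65), Avpr1a (1.86), Acss2 (1.28), Insig1 (1.09), Pemt (0.70), Bhmt2 (0.55), Gnmt (1.01), Gckr (0.76), Mmp8 (2.78), Ahsg (0.76) and Ass1 (0.98).

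Single libraries lay far from the others of their group in 23 of 240 groups tested, where chance gives about 1 in 20. These were, in CPM, Fabp4 (24.7) and Gpr12 (4.99) in HF_C 1, Cyp2c54 (52.5), Atp2b2 (2.38), Mup17 (15.6), Slco1a1 (109.6) and Ltf (4.94) in HF_C 2, Otop1 (0.0692) in HF_C 4, Cd163 (4.18) in HF_C 5, Cfd (0.445) and Ltf (1.98) in HF_KO 1, Clec2h (6.63) and Aqp4 (31.2) in HF_KO 3, Fgf21 (36.6) in HF_KO 4, Slc22a29 (1.61) in HF_TZD_C 1, Col1a1 (269) in HF_TZD_C 2, Rbm24 (0.491) in HF_TZD_C 4, Cfd (6.50) in HF_TZD_KO 2, Mup17 (5.85) in HF_TZD_KO 3, Rbm24 (0.769) in HF_TZD_KO 5, Trem2 (2.29) and Mmp7 (0.432) in LF_C 2 and Cyp2c69 (13.1) in LF_C 4. Dixon's test was first run over 340 groups, every named gene in all groups, with 35 past the limit, and was narrowed after that, for genes other than the fixed ones, to the groups in which they are named.

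In each of the comparisons and in the test of the difference, no other of 100 splits of the libraries gave as many genes (1 of 100, the real one). This argues against chance for the gene counts of the comparisons. The real counts were 6003, 152, 792, 107, 2387 and 376 for HF_C over LF_C, HF_KO over HF_C, HF_TZD_C over HF_C, HF_TZD_KO over HF_KO, HF_TZD_KO over HF_TZD_C and the difference, and the highest of other splits gave 3289, 22, 1, 1, 1 and 13. The split with 3289 genes exchanged 1 HF_C with 1 LF_C library. For lists, 11, 14, 61, 50, 5 and 2 of 100 splits gave as many as the real 20, 17, 12, 14, 21 and 19, with 24, 19, 18, 20, 21 and 19 lists in the highest other split. Splits for the difference exchanged rosiglitazone labels within each genotype, which also breaks the drug effect that the genotypes share. They therefore cannot decide whether chance gave the difference, for genes or lists, and another split gave the same 19 lists. In the comparisons such numbers also arise by chance, since other splits gave a median of 12 to 15 lists.

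Pparg counts were higher, not lower, in libraries labelled knockout (0.99 in HF_KO over HF_C). Labels exchanged between these groups are argued against, since the PPARγ-linked list had a mean of -0.50 (SE 0.156) in libraries labelled knockout, where an exchange needs a higher mean. More cells of another type carrying Pparg needs a cell type list to rise as far as Pparg. With an SE from the SD, the adipocyte list reached highest (-0.19, SE 1.20), its few members spread by the fall of Cfd (-5.77). As the list fell (score 0.23 in HF_C, -0.62 in HF_KO), this argues against more adipocytes. With an SE from the median absolute deviation (adipocyte 0.209), chosen after that, the erythrocyte list reached highest (0.40, SE 0.0844), below Pparg. Transcripts of Pparg that keep the exons outside a deletion, or a genotype effect in other cells, stay open and may be seen in reads per exon.

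HF_TZD_KO replicate 5 lay towards LF_C, at a position of 0.167 on genes changed by the diet, where 0 is the LF_C mean, 1 the mean of the other HF_TZD_KO libraries, and these lay at 0.750 to 1.25. The tests written first, on genes called in HF_KO over HF_C, left a wrongly labelled LF_C library undecided (0.376, SE 0.155, LF_C -0.105 to 0.138, other HF_TZD_KO 0.842 to 1.04), and the difference of 0.210 (SE 0.155) from the position on diet genes is what LF_C material mixed in predicts. Gene sets chosen after these values argue against both: on genes not called under the diet it lay at 0.818 (SE 0.110, LF_C -0.141 to 0.242), 0.652 (SE 0.110) away, and on cholangiocyte genes at 0.544 (SE 0.0561, LF_C -0.116 to 0.115), 0.377 (SE 0.0567) away, which need shares of HF_TZD_KO material of at least 0.593 and 0.359 where diet genes allow up to 0.244. Thinning keeps expected gene shares, so it cannot decide on depth (position 0.163, others 0.752 to 1.23). A treated mouse with a smaller effect of the diet stays open and was not tested.

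In HF_TZD_KO over HF_TZD_C, hepatocyte genes were higher and macrophage and matrix genes lower. A lower share of all other cells, which would lower their lists alike, is argued against, since the cholangiocyte (0.04) and recruited macrophage (-0.72) lists lay 0.76 apart (SE 0.114). HF_TZD_KO replicate 5 as the whole cause is argued against, since without it the hepatocyte, recruited macrophage and matrix medians were 0.74, -0.51 and -0.38, the last 2 having moved from -0.72 and -0.51. Thinned medians (0.75, -0.72 and -0.52) likewise cannot decide on depth. A change in particular cell types, and an effect of the genotype as labelled in treated mice, stay open and were not tested.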

How the results depend on the processing

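Thinning and library totals without a scaling factor were chosen after the data were seen, and the other alternatives before. Under RLE scaling, 5840, 147, 767, 106, 2375 and 371 of the 6003, 152, 792, 107, 2387 and 376 genes changed in HF_C over LF_C, HF_KO over HF_C, HF_TZD_C over HF_C, HF_TZD_KO over HF_KO, HF_TZD_KO over HF_TZD_C and the test of the difference were called again, and thinned to the lowest depth 5593, 130, 733, 98, 2272 and 345. No gene shared with an alternative changed direction. With a log2 fold change of at least 1 the counts were 2293, 37, 114, 31, 524 and 90, fewer by construction. DESeq2 called 370, 1219, 649 and 733 genes in HF_KO over HF_C, HF_TZD_C over HF_C, HF_TZD_KO over HF_KO and the difference. A fit of all 24 libraries gave 90, 387 and 440 in the first 3 of these, and no filter 201 in HF_TZD_KO over HF_KO. Without a scaling factor 220 and 3656 genes changed in HF_TZD_KO over HF_KO and over HF_TZD_C. Between 19.5 and 28.7 M reads, depth limits the genes too low for the filter, which were not tested. The causes were not tested.

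Leaving out 1 library gave 64 to 186 genes in HF_KO over HF_C, 497 to 930 in HF_TZD_C over HF_C, 0 to 223 in HF_TZD_KO over HF_KO, 1569 to 2695 in HF_TZD_KO over HF_TZD_C and 191 to 467 for the difference. The Kupffer cell list in HF_KO over HF_C turned, passing upwards without HF_C replicate 5 (adjusted p = 0.0393) and downwards without HF_C replicate 4 (0.0438, other alternatives 0.228 to 0.972). Camera with an estimated correlation called 0, 1, 1, 0, 1 and 2 of the 27 lists, in the order of comparisons above. Fry called 1, 2, 6 and 3 lists in HF_KO over HF_C, HF_TZD_C over HF_C, HF_TZD_KO over HF_KO and the difference. The correlation of labelled knockout effects with and without rosiglitazone was 0.168 with DESeq2, whose correlations take in all genes with a count, without the filter. That of diet and rosiglitazone effects was 0.0431 over genes of at least 2 CPM, -0.269 with DESeq2 and -0.165 to 0.0482 with 1 library left out. A replicate block gave 386 genes in HF_TZD_C over HF_C, 0 in HF_TZD_KO over HF_KO by edgeR (1963 at an unadjusted p under 0.05, and DESeq2 without the block 649) and 236 for the difference. Pairing by number stays open. Same-number residuals correlated by -0.18 to 0.146. In HF_KO over HF_C their mean was 0.0507 (negative in other comparisons, other numbers -0.0127) and 2 of 5 pairs passed 0.1.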

Other observations

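The cholesterol synthesis score (mean over members of log2 CPM minus the mean of all libraries, ± SD) was 0.31 ± 0.510 in LF_C, -0.37 ± 0.356 in HF_C, 0.19 ± 0.275 in HF_KO, -0.69 ± 0.102 in HF_TZD_C and 0.62 ± 0.457 in HF_TZD_KO, with n = 4 in LF_C and n = 5 in the other groups. LF_C replicate 4 stood at -0.32 (others 0.13 to 0.78) and HF_C replicate 2 at 0.21 (others -0.73 to -0.35). The cell cycle score was, in the same order, -0.59 ± 0.336, 0.36 ± 0.220, 0.31 ± 0.161, 0.19 ± 0.0689 and -0.38 ± 0.376, the values of HF_TZD_KO lying nearer to LF_C than those of the other groups on the HFCF diet. HF_TZD_KO replicate 5 stood at -1.03 in this score, and the other 4 at -0.33 to -0.10, the group mean without it being -0.22.

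The authors' own adjusted p passed 0.05 for 6465, 368, 1212, 645 and 3038 genes in HF_C over LF_C, HF_KO over HF_C, HF_TZD_C over HF_C, HF_TZD_KO over HF_KO and HF_TZD_KO over HF_TZD_C. Of the edgeR calls, 5864, 151, 788, 107 and 2383 were among them, all in the direction the authors give. The authors' table likewise holds a higher Pparg in libraries labelled knockout (0.90 and 0.74 without and with rosiglitazone).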
